A study of Homo sapiens with 6 samples.

How the data were processed

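Total RNA of Hs578T cells was hybridised to 6 Affymetrix HuGene 2.0 arrays, 3 of cells given a non-targeting siRNA and 3 of cells given CSRP2 siRNA. Per the labels' protocols, 150000 cells were plated per well of a 6-well plate in DMEM with 10% serum and 0.01 mg/ml insulin and transfected with a lipid reagent. After 24 h, 100000 cells per well were moved to a 24-well plate, and RNA was taken 48 h later. 100 ng of RNA entered the labelling reaction, and 5.5 ug of cDNA was fragmented and labelled with biotin. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

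The authors deposited 1 value per probe set and array, on a log2 scale as judged from the values: base 2 was inferred because base e or 10 would take the highest value past the range of a 16-bit scanner. Partek is named per the submitters' processing notes, with no version or role. Background correction, summarisation, normalization between arrays and genome build are not given in the sources used here. The quartiles differ between arrays, so the values as held here are not quantile normalized to 1 distribution. No detection calls were used here, so a probe set near background has no marked limit. A fold at a dim level can understate the change.

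Probe sets were named through the platform's annotation table: 16098 of 53617 had 1 gene symbol, none had several and 37519 had no gene listed there, which leaves them unnamed here rather than without a gene. The gene identifiers of all 16098 matched a RefSeq gene table (GRCh38.p14), which was used for current symbols and biotypes and for no coordinates. The probe set with the highest mean over the 6 arrays stood for each gene, which gave 14884 genes, with no filter on dim genes and no further normalization. Every value column was mapped to a sample.

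Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, two-sided. CSRP2 and its relatives also had an exact permutation test of 3 against 3 values. The 31 gene lists, the tests of genes and lists, the rule for naming genes and the alternatives, except those joining a scaling with the replicate block, were fixed before the data were examined. The comparison with random lists and the tests in the closing section other than the splits of the arrays were not. 29 lists with at least 8 measured genes were tested with camera at a preset correlation of 0.01. The replication-dependent histone list had 0 measured genes and the silencing machinery list had 6, none of them past the threshold (1, XPO5, fell with the replicate block), so neither was tested. Camera with an estimated correlation was run beside it, and none of the 13 calls held there. The rotation test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 15 lists: 8 of the 13, and 7 that camera did not call. The replication, immediate early, NF-kB, NRF2 and ribosomal lists were called by camera and not by fry. For each list, 10000 random lists of equal size were drawn within 100 ranks of each member's mean expression.

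The genes named are CSRP2, CSRP1 and CSRP3; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is above the median of all genes, leaving out small and uncharacterised RNA genes; up to 4 members with the smallest adjusted p of each list called or discussed; and list members past the threshold with a log2 difference of at least 1 in size. Each tested list is discussed so that its result is given, called or not. CKS2, RSAD2, IFIT1, SAMD9 and SKIL lie outside this rule and were chosen after their values were seen, as were XPO5, FBLIM1, LIMK1, PDLIM1, PFN2, CYFIP1, ABI1, BAIAP2, SH3PXD2A, ABL2, TPM4, CNN2, TWIST2, PRRX1 and ADAM17, which passed only with the replicate block.

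Replicate numbers are shared between the groups, and the labels do not tie a number to a plate or day. Deviations from the group means correlated across genes between same-numbered arrays at 0.30, 0.19 and 0.32, and between differently numbered arrays at -0.26 to 0.05. Each same-numbered pair was above 0.1, so the numbers were taken to pair the arrays, from the data and not the labels. Deviations cancel out within a group, so the low values between differently numbered arrays follow in part from the high ones and are not separate evidence. With so few arrays a match of the numbers by chance is not excluded, and the fit with the block is an alternative. The fit with the replicate number as a block, adjusted over all genes, is given beside each list in which it changed how many members passed.

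The fit was tested on simulated data of 14884 genes with the real spread of each gene and 200 changed genes. Genes were drawn independently of each other, with no paired or outlying arrays, so the rates may not hold for the real arrays. In the simulation the fit recovered 16.4% of changes of 0.5, 88.1% of changes of 1 and 98.5% of changes of 2 log2 units. There 9 of the 144 genes called were unchanged ones. The alternatives were quantile, cyclic loess and median scaling, filters on the dimmest 25% and 50% of genes, other ways of choosing probe sets, an intensity trend, robust moderation, array weights, no moderation, the replicate block and leaving out each array.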

Results

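Gene expression was measured in Hs578T cells, an established human breast cancer line of mesenchymal appearance that lacks the oestrogen receptor. The cells had been transfected with a small interfering RNA against CSRP2 or with a non-targeting control RNA. CSRP2 encodes cysteine and glycine rich protein 2, a LIM domain protein that binds and bundles actin filaments. Each group held 3 arrays, numbered 1 to 3 in the labels, and every array gave 1 log2 value for each of 53617 probe sets. The medians over all probe sets ran from 2.70 (siControl 2) to 2.82 (siCSRP2 1), and all siCSRP2 medians (from 2.80) lay above all siControl medians (up to 2.76). The SD over probe sets was smaller on all siCSRP2 arrays (1.29 to 1.32) than on all siControl arrays (1.35 to 1.38). Pairs of arrays correlated across genes at r = 0.916 to 0.988, and no pair shared more than 2 identical values over the 53617 probe sets, so each array was counted as 1 sample. The number of arrays limits the precision of every value below.

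The first principal component, with 63.2% of the variance, placed the 3 siCSRP2 arrays at 14.01, 20.03 and 30.7. siControl 1 and siControl 2 lay at -31.5 and -31.2, and siControl 3 lay between the groups at -2.05. siControl 3 correlated about as well with the siCSRP2 arrays (mean r = 0.966) as with the other controls (mean r = 0.967).

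**Figure D1:**
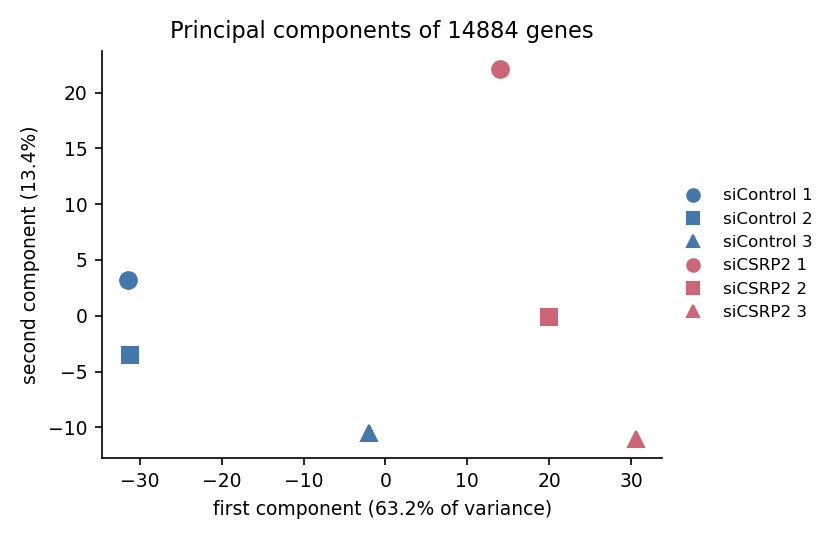
Scores of the 6 arrays on the first (63.2% of variance, x axis) and second (13.4%, y axis) principal components of 14884 genes, with colour for group and marker shape for replicate number. siControl 3, at -2.05 on the x axis, lies apart from the other controls, which are at -31.5 and -31.2.

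The knockdown target was examined before any other gene. CSRP2 (probe set 16767837) measured 3.69, 4.01 and 4.35 on the siControl arrays and 3.25, 3.76 and 4.26 on the siCSRP2 arrays, with group means of 4.02 ± 0.33 and 3.76 ± 0.51 (SD, n = 3). The difference was -0.26 on the log2 scale (SE 0.26, 95% interval -0.84 to 0.32), and the groups overlapped. CSRP2 was lower on the siCSRP2 array in 3 of 3 pairs of equal replicate number, but the difference did not pass the test (limma, adjusted p = 0.583, and 0.188 with the replicate number as a block). The exact permutation test gave a two-sided p of 0.5, where 0.1 is the smallest that 3 against 3 can reach. Given the spread between these arrays, the 95% interval excludes a fall of more than 1.8-fold in the signal of this probe set. It sets no bound on the fall of the transcript, since no background value was at hand. The target therefore does not check the labels, and siCSRP2 below means the arrays labelled siCSRP2.

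The related LIM proteins were given by 1 probe set each. CSRP1 measured 4.70 ± 0.49 on siControl and 4.0 ± 0.50 on siCSRP2 arrays (SD, n = 3), a log2 difference of -0.70 that did not pass the test (SE 0.29, adjusted p = 0.191), though it did with the replicate number as a block (adjusted p = 0.00491). CSRP3, the muscle member of the family, measured 2.51 ± 0.12 and 2.73 ± 0.20, below the median of all gene means (2.99), with an adjusted p of 0.345 (0.241 with the block).

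**Figure D2:**
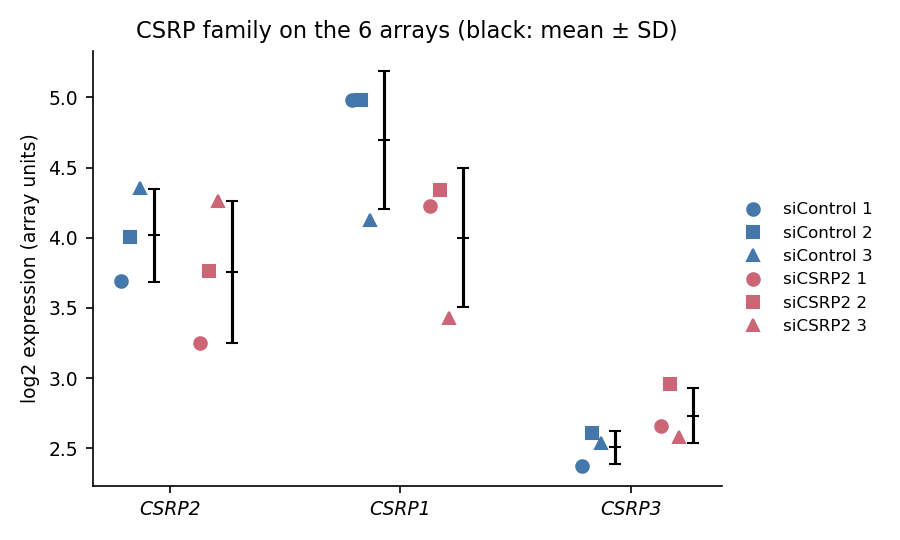
log2 values of CSRP2, CSRP1 and CSRP3 (x axis) on the 6 arrays (y axis, array units), with colour for group, marker shape for replicate number, and black bars for the group mean ± SD. The CSRP2 values of siCSRP2 arrays (3.25 to 4.26) overlap those of siControl arrays (3.69 to 4.35).

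The comparison of siCSRP2 with siControl asks which transcripts differ in cells given the RNA against CSRP2. MMP13, a collagenase, fell 12.1-fold, from 6.39 ± 0.67 to 2.80 ± 0.34 (SD, n = 3; log2 difference -3.59, SE 0.31, adjusted p = 0.00228). The protocadherin PCDH18 fell 9.72-fold (log2 difference -3.28, SE 0.35) and the chemokine CCL2 fell 6.33-fold (-2.66, SE 0.63), a value that rested on single arrays: 11.5-fold without siControl 3 (-3.52) and 4.15-fold without siControl 2 (-2.05, adjusted p = 0.144). Among the largest rises were the transcription factor CREB5 (3.08-fold, log2 difference 1.62, SE 0.27) and the interferon-induced ubiquitin-like ligase HERC5 (2.72-fold, 1.44, SE 0.21). Falls outnumbered rises: of 14884 genes, 119 rose and 974 fell (1093 past adjusted p 0.05), and 27 rose and 258 fell by at least 2-fold.

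The other genes with the largest falls were SERTAD4 (log2 difference -2.44), the endoplasmic reticulum lectin MLEC (-2.43, and -1.39 as the mean of its probe sets), the mitotic kinesin KIF20A (-2.37), the adhesion receptor VCAM1 (-2.20), catalase, CAT (-2.18), METTL9 (-2.10), SECTM1 (-2.01), serine racemase, SRR (-1.98), and the microtubule-associated EML1 (-1.95). VCAM1 went from 5.76 ± 0.46 to 3.56 ± 0.13 (SD, n = 3). METTL9 and EML1 had the smallest adjusted p of these genes, 0.000854 for both. The remaining largest rises were PDCL3 (1.55), the Wnt receptor FZD4 (1.54), the phosphatase DUSP8 (1.52), the chemokine CCL3L1 (1.52), the hormone FGF21 (1.48), PMAIP1, which encodes the pro-apoptotic NOXA (1.42), the homeobox gene HOXB9 (1.38), STX11 (1.36), the long non-coding RNA LEISA1 (1.34), and the prostaglandin E2 receptor PTGER4 (1.31). Adjusted p for these 24 genes ran up to 0.0448 (DUSP8). MMP13, PCDH18, SERTAD4, MLEC, VCAM1, CAT, METTL9 and EML1, 8 of the 12 largest falls, passed in each fit that left 1 array out, as did LEISA1 alone of the 12 largest rises, while CCL2 passed in 1 of these 6 fits.

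**Figure D3:**
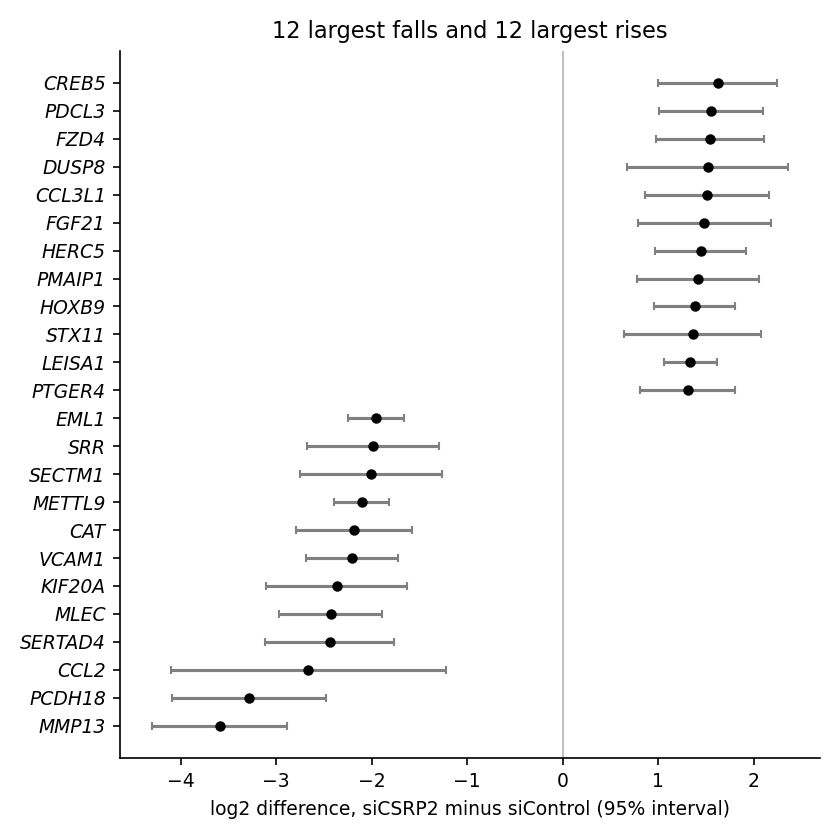
log2 differences, siCSRP2 minus siControl (x axis), of the 12 largest falls and 12 largest rises among genes chosen by a fixed rule, with 95% intervals as bars and n = 3 arrays per group. Differences range from -3.59 (MMP13) to 1.62 (CREB5).

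The groups did not overlap for 1712 genes that were higher and 2410 that were lower, 27.7% of genes against 10% by chance. The number past the threshold depended on single arrays: it was 157 without siControl 1, 91 without siControl 2, 2620 without siControl 3, 194 without siCSRP2 2 and 285 without siCSRP2 3. Of 140 named genes other than CSRP2, 94 passed the test, and of these 67 did not pass without siControl 1, 79 without siControl 2, 1 without siControl 3, 26 without siCSRP2 1, 64 without siCSRP2 2 and 59 without siCSRP2 3. With the replicate number as a block, 398 genes rose and 1950 fell (2348 in all). The split was 89.1% falls on the values as deposited, 76.0% after quantile normalization (210 rose, 666 fell) 77.7% after cyclic loess (197 rose, 687 fell) and 94.5% after median centring (86 rose, 1471 fell).

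Genes of mitosis and of the G2/M phase were lower in siCSRP2. Of 42 measured members, 16 fell, 1 rose and 25 did not pass the test, with a median log2 difference of -0.66. The members that fell included KIF20A (-2.37), the cyclin CCNA2 (-1.51, 2.85-fold), the kinesin KIF11 (-1.38, 2.6-fold), the topoisomerase TOP2A (-1.36, 2.56-fold), the kinase PLK1 (-1.27, 2.42-fold), the transcription factor FOXM1 (-1.23, 2.34-fold) and the spindle protein NUSAP1 (-1.09, SE 0.11, 2.13-fold). CKS2, a cyclin-dependent kinase subunit chosen after its values were seen, rose (0.50). Adjusted over the list alone, 32 members fell and 1 rose, and with the replicate number as a block 23 fell and 1 rose over all genes. The camera test with a preset correlation called the list (adjusted p = 2.99e-12), and the call was lost at adjusted p = 0.336 with an estimated correlation. None of 10000 random lists matched on brightness had a median as low. Relative to the siControl mean, the list median was -0.84, -0.42 and -0.71 on the siCSRP2 arrays and 0.14, 0.17 and -0.30 on siControl 1, 2 and 3.

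DNA replication and G1/S genes were lower as well, with a median of -0.45 over 30 measured members. 8 fell, none rose and 22 did not pass, and 15 fell when adjusted over the list alone and 14 with the replicate block. Thymidylate synthase, TYMS, fell 3.1-fold (log2 difference -1.63, SE 0.28), the helicase subunit MCM4 fell 2.3-fold (-1.20), the sliding clamp PCNA fell 2.26-fold (-1.17) and cyclin E2, CCNE2, fell 1.59-fold (-0.67). The list was called at adjusted p = 1.44e-07, lost at adjusted p = 0.336 with an estimated correlation and at 0.0747 by the rotation test fry, and none of 10000 matched random lists had a median as low. On siControl 3 this list lay at -0.38 relative to the siControl mean, beside -0.39 on siCSRP2 2, and at 0.17 on both other controls.

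Mesenchymal markers were lower, with 6 of 13 measured members falling, none rising and 7 not passing, and a median of -0.59. The receptor tyrosine kinase AXL fell 3.32-fold (8.32 ± 0.37 to 6.59 ± 0.41, SD, n = 3; log2 difference -1.73, adjusted p = 0.00833), the transcription factor SNAI2 fell 2.32-fold (-1.21), the intermediate filament vimentin, VIM, fell 1.77-fold (-0.82), S100A4 fell 1.7-fold (-0.77) and fibronectin, FN1, fell 1.5-fold (-0.59). Adjusted over the list alone, 10 members fell, and 8 fell with the replicate block, which added TWIST2 and PRRX1. The list was called at adjusted p = 8.03e-06 and lost at adjusted p = 0.332 with an estimated correlation, and 14 of 10000 matched random lists had a median as low. All siControl arrays lay between -0.05 and 0.13 on this list relative to their mean, and the siCSRP2 arrays between -0.67 and -0.45. Among 22 measured epithelial and luminal markers none passed the test, over all genes or adjusted over the list alone, and camera did not call the list (adjusted p = 0.102, median 0.13, and 0.07 without siControl 1, 0.08 after quantile normalization, 0.07 after cyclic loess and 0.04 after median centring), though fry called it higher (adjusted p = 0.0385). Among random lists matched on brightness, the epithelial median as reported lay at percentile 98.2. The keratin KRT18 fell with the replicate block (-0.74, adjusted p = 0.00746).

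Matrix genes fell singly, and their lists were called lower by fry (adjusted p = 0.0385 for both) and not by camera. As reported, their medians were small, -0.12 for collagens and matrix proteins and -0.02 for proteases, and 13.6% and 60.9% of matched random lists had a median as low. The collagen median varied with the setting: -0.28 and -0.36 with the dimmest 25% and 50% of genes left out, -0.20 over every probe set and -0.03 with array weights. The protease median was -0.12 with the dimmest 50% left out and -0.02 after quantile normalization. With 1 array left out, the medians lay between -0.21 (without siControl 1) and -0.09 (without siControl 3) and between -0.14 (without siCSRP2 2) and -0.03 (without siControl 2). Of 15 measured collagens and matrix proteins, 5 fell and none rose: the proteoglycans lumican, LUM (-1.43), decorin, DCN (-1.10), and versican, VCAN (-0.88), with thrombospondin 1, THBS1 (-1.28), and FN1 (-0.59). Camera gave an adjusted p of 0.0705, which passed without siControl 1 (0.0123), without siCSRP2 2 (0.0309) and over every probe set (0.000287), and 5 members fell when adjusted over the list alone. Of 23 matrix proteases and inhibitors, which bear on the matrix-degrading role described for CSRP2, 3 fell and none rose: MMP13, the collagenase MMP1 (-1.43, 2.7-fold) and ADAM15 (-0.94). Camera did not call that list (adjusted p = 0.283) except over every probe set (0.0092), and 5 members fell and 2 rose when adjusted over the list alone. The cathepsin CTSL also fell (-0.77) and ADAM17 rose (0.47) with the replicate block.

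Camera also called lower the 4 cytoskeletal lists closest to the known functions of CSRP2, though none of these calls held with an estimated correlation. Of 22 measured invadopodia genes, which serve the actin-rich protrusions that degrade matrix, 4 fell, none rose and 18 did not pass: the scaffold SH3PXD2B (-1.0, SE 0.17), ADAM15 (-0.94), cortactin, CTTN (-0.58), and ENAH (-0.48). Of 24 actin assembly and bundling genes, 6 fell and none rose, among them the formins FMNL2 (-0.75), DIAPH3 (-0.55) and DIAPH2 (-0.52) and the cofilin CFL2 (-0.62). Of 16 SRF and MRTF targets, 4 fell and 1 rose: TGFB1I1 (-1.15), vinculin, VCL (-0.71), caldesmon, CALD1 (-0.54), and DSTN (-0.54) fell, and the matricellular gene CCN2 rose (0.62). Of 30 LIM domain cytoskeletal proteins, 4 fell and none rose: TGFB1I1, LIMCH1 (-0.63), LMO7 (-0.56) and LIMA1 (-0.47).

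Adjusted over the list alone, the falls numbered 7 for invadopodia, 9 for actin assembly, 9 for SRF and MRTF targets (with 2 rises) and 4 for LIM proteins, and actin assembly had 1 rise. With the replicate block, over all genes, 6 invadopodia genes fell (BAIAP2 and SH3PXD2A added) and ABL2 rose, 8 actin genes fell (PFN2 and CYFIP1 added) and ABI1 rose, 6 SRF targets fell (TPM4 and CNN2 added), and 8 LIM genes fell (FBLIM1, LIMK1, PDLIM1 and CSRP1 added). The medians were -0.25, -0.23, -0.33 and -0.12, and camera called the lists at adjusted p = 0.00216, 0.0049, 0.0117 and 0.035. All 4 calls were lost at adjusted p = 0.336 with an estimated correlation, and all 4 were lost after quantile normalization or cyclic loess and with the dimmest 50% of genes left out. In the order above the medians were nearer 0 after quantile normalization (-0.08, -0.16, -0.16, -0.05) and cyclic loess (-0.10, -0.15, -0.17, -0.07), but as large or larger with the dimmest 50% left out (-0.25, -0.25, -0.37, -0.16), and the LIM median was -0.21 after median centring. Among random lists matched on brightness, 24.7% had a median as low as the invadopodia list, 47.3% as low as the LIM list, 6.95% as low as the actin list and 4.07% as low as the SRF list. The LIM call was also lost without siControl 2 (adjusted p = 0.0703), siControl 3 (0.0808), siCSRP2 1 (0.0566) or siCSRP2 3 (0.0515), although its median stayed between -0.14 and -0.11 in these fits. The invadopodia median was -0.16 without siControl 2.

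The NRF2 and glycolysis lists were lower too. Of 10 measured NRF2 targets, 3 fell and none rose, also when adjusted over the list alone: transaldolase, TALDO1 (-1.34), glutathione reductase, GSR (-1.25), and transketolase, TKT (-0.50). The list median was -0.36 (adjusted p = 0.00248, and adjusted p = 0.336 with an estimated correlation), and siControl 3 lay at -0.24 relative to the siControl mean. The median was -0.54 without siControl 3, fry gave an adjusted p of 0.0539, camera gave 0.0508 with the dimmest 50% of genes left out (median -0.45), and 5.76% of matched random lists had a median as low. Of 9 glycolysis genes, 2 fell and none rose, the isomerase GPI (-0.73) and the lactate dehydrogenase subunit LDHB (-0.66), and 3 fell when adjusted over the list alone. The replicate block added LDHA (-0.41) and PGK1 (-0.52), for 4 falls. The glycolysis median was -0.35 (adjusted p = 0.0237, lost at adjusted p = 0.336 with an estimated correlation), and 8.5% of matched random lists had a median as low. The call was lost at 0.157 without siControl 3, where the median was -0.30, and after quantile normalization or cyclic loess (median -0.25 in both). It was also lost with the dimmest 25% (0.082) or 50% (0.326) of genes left out, though the median stayed at -0.35.

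The 4 lists called higher held few genes that passed on their own. The immediate early genes, induced within minutes of a stimulus, had a median of 0.42 over 23 measured members, yet none rose and 1 fell, the ERK phosphatase DUSP6 (-0.77); adjusted over the list alone, 1 rose and 1 fell. With the replicate block 8 rose, among them the transcription factor KLF4 (1.06, adjusted p = 0.00861) and the signalling inhibitors SPRY2 (1.07, 0.011) and SPRY4 (0.86, 0.0162). The median was 0.21 without siControl 1, 0.72 without siControl 3 and 0.71 with array weights. The NF-kB and inflammatory cytokine genes had a median of 0.26 over 19 members, of which the chemokine CCL5 rose (0.64) and CCL2 fell (-2.66); adjusted over the list alone, 2 rose and 1 fell. With the replicate block 7 rose, among them the cyclooxygenase PTGS2 (1.54, adjusted p = 0.00241) and the chemokine CCL20 (1.06, 0.00185), and the median was 0.41 without siControl 3, 0.43 with the dimmest 50% of genes left out and 0.47 over every probe set. For the immediate early and NF-kB lists the camera adjusted p was 0.00138 and 0.00573, it was 0.356 and 0.336 with an estimated correlation, and fry called neither (0.206 and 0.175). siControl 3 was high on both lists, at 0.51 and 0.29 relative to the siControl mean, where siCSRP2 arrays lay between 0.35 and 0.59 and between 0.07 and 0.42. The 33 cytosolic ribosomal protein genes (median 0.11, adjusted p = 0.0299) and 12 leukocyte markers (median 0.15, adjusted p = 0.0419) had no member past the threshold, over all genes or adjusted over the list alone, and both calls were lost at adjusted p = 0.336 with an estimated correlation. The ribosomal call was lost without siControl 3 (adjusted p = 0.0686, median 0.10), without siCSRP2 3 (0.0874, median 0.08) and by fry (0.0529), and the median was 0.20 after quantile normalization, 0.18 after cyclic loess and 0.02 after median centring. The leukocyte call was lost without siControl 2 (0.0703, median 0.16), without siCSRP2 1 (0.0902, median 0.13) and after quantile normalization (0.138) or cyclic loess (0.132, median 0.14 in both), and fry called it (0.0385). Its median was 0.07 after median centring. That scaling moves every list median by the same amount, and camera still called the leukocyte (adjusted p = 0.0361) and ribosomal (0.037) lists there. Among random lists matched on brightness, the immediate early and NF-kB medians lay at percentile 100, the ribosomal median at 97.8 and the leukocyte median at 97.2.

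**Figure D4:**
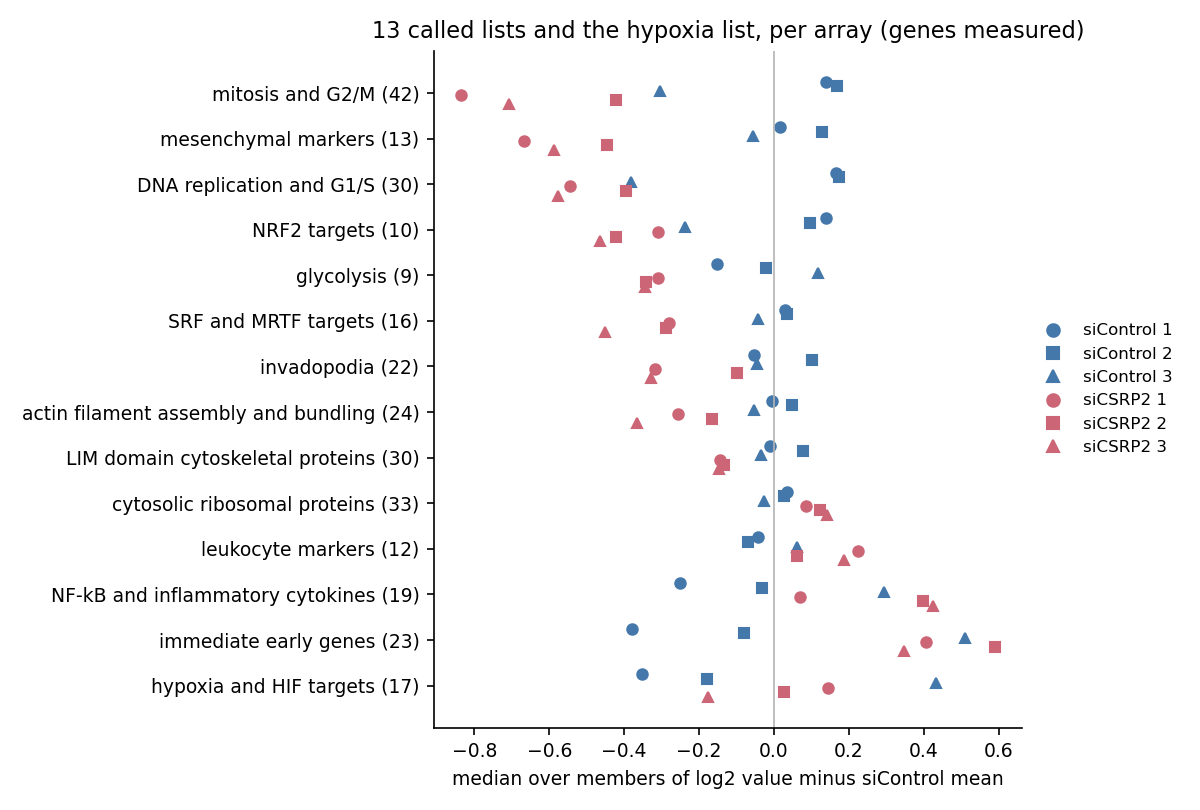
Median log2 value of each called list's members, and of the hypoxia list, on each of the 6 arrays relative to the siControl mean (x axis, log2 units), with the list and its number of measured genes on the y axis, colour for group and marker shape for replicate number. On the mitosis list the siCSRP2 arrays lie between -0.84 and -0.42, and siControl 3 lies at -0.30.

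The type I interferon genes, which transfected RNA can induce, went both ways. Of 28 measured members, HERC5 (1.44), IFIT2 (0.88), RSAD2 (0.89), IFIT1 (0.82) and SAMD9 (0.78) rose, while XAF1 (-1.19), BST2 (-0.90) and IRF9 (-0.51) fell, of which RSAD2, IFIT1 and SAMD9 were chosen after their values were seen. The list median was 0.18, but 0.08 without siCSRP2 3, 0.27 without siCSRP2 1, 0.30 with the dimmest 50% of genes left out and 0.09 after median centring. The list was not called (adjusted p = 0.184), and 8 rose and 6 fell when adjusted over the list alone, and likewise 8 and 6 with the replicate block. It was called after quantile normalization (adjusted p = 0.0224), cyclic loess (0.0223), with the dimmest 50% of genes left out (0.00447) and without siCSRP2 1 (0.0183), and the adjusted p was 0.565 with an estimated correlation. The hypoxia and HIF targets, of interest because CSRP2 has been described as induced by low oxygen, were not called (17 measured, adjusted p = 0.602). EGLN1 (-0.51) and STC2 (-0.48) fell and none rose, also when adjusted over the list alone, while with the replicate block the demethylase KDM3A rose (0.80, adjusted p = 0.0395) and LDHA and PGK1 fell too. On siControl 3 the hypoxia list was at 0.43 relative to the siControl mean, above the other arrays, which lay between -0.35 and 0.14.

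Camera called none of the remaining lists, while fry called YAP targets (adjusted p = 0.0378), p53 targets (0.0385) and heat shock proteins (0.00857) lower and skeletal and cardiac muscle markers higher (0.0378). None of these 4 medians stood out from random lists matched on brightness, of which 25.8%, 19.5% and 35.2% were as low as YAP (-0.16), p53 (-0.16) and heat shock (-0.19), and the muscle median of 0.08 was near their typical 0.07. After quantile normalization the YAP, p53, heat shock and muscle medians were -0.01, -0.02, -0.11 and 0.00, and after cyclic loess -0.03, -0.05, -0.13 and -0.01. Median centring, which moves every list median by the same amount, gave -0.25, -0.24, -0.28 and -0.01. With 1 array left out, YAP reached -0.05 (without siCSRP2 2) and -0.09 (without siControl 3), p53 reached -0.08 (without siCSRP2 3) and -0.09 (without siCSRP2 1), and muscle reached 0.04 (without siControl 2) and 0.12 (without siCSRP2 3). The values given next for each list are camera's. YAP and TEAD targets (adjusted p = 0.184) had 4 falls, AXL, CCDC80 (-1.22), FJX1 (-1.23) and DOCK5 (-0.62), and 1 rise, CCN2. TGF-beta response genes (adjusted p = 0.729) had 3 falls, THBS1, SNAI2 and LTBP1 (-0.53), and 2 rises, CCN2 and SKIL (0.90), the last chosen after its values were seen. The TGF-beta median of 0.16 lay at percentile 97.6 of matched random lists, but was 0.05 without siCSRP2 2. Among p53 targets (adjusted p = 0.602), PLK2 (-1.11) and TP53INP1 (-0.88) fell and AEN (0.55) rose. The heat shock proteins HSPB1 (-1.52, 2.88-fold) and HSPA4L (-0.97) fell (list adjusted p = 0.0743, and 0.0432 without siCSRP2 3), as did COX6A1 (-1.60, 3.04-fold, and -0.86 as the mean of its probe sets) in oxidative phosphorylation (0.102), TNS3 (-1.25) and VCL among integrin and focal adhesion genes (0.612), and FADS1 (-0.51) among cholesterol synthesis genes (0.734). In the ATF4 and unfolded protein response list (0.512), MANF (-0.61) and TRIB3 (-0.58) fell and asparagine synthetase, ASNS (0.78), rose. The endothelial transcription factor ERG rose (0.52; endothelial list 0.129), and no skeletal or cardiac muscle marker (0.105) and no gene of ribosome biogenesis (0.731) passed. Adjusted over the list alone, the falls and rises numbered 5 and 1 for YAP, 3 and 4 for TGF-beta, 4 and 2 for p53, 2 and 1 for heat shock, 4 and 0 for oxidative phosphorylation, 3 and 0 for integrins, 0 and 0 for cholesterol synthesis, 5 and 2 for ATF4, and 0 and 1 for the endothelial list, and were 0 for the muscle and ribosome biogenesis lists. With the replicate block, over all genes, they numbered 3 and 5 for TGF-beta, 4 and 1 for p53, 2 and 1 for heat shock (HSPB8 rose), 4 and 0 for oxidative phosphorylation, 4 and 0 for integrins, 4 and 1 for cholesterol synthesis, 4 and 2 for ATF4, and 1 and 1 for ribosome biogenesis (NCL fell, ODC1 rose).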

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

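The chance splits were planned; the tests of CSRP2, of the excess of falls and of the lists against matched random lists were chosen only after the results were seen, and none of their bounds was fixed in advance.

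Probe sets with no gene listed took no part in the comparisons of named genes, and 34 of 37519 were higher and 209 lower in siCSRP2 (limma over every probe set, adjusted p below 0.05), against 17 higher and 246 lower of 16098 probe sets with a gene.

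CSRP2 itself did not separate the groups. A swap of the labels of siControl 1 or 2 with a siCSRP2 array is argued against by their place between the other siControl arrays (0) and the siCSRP2 arrays (1) over 500 genes chosen without the array, whose upper quartile reached 0.05272, below the lower quartile of each siCSRP2 array (lowest 0.49, siCSRP2 1). That place takes the labels of the other arrays as given. It cannot reveal a wrong label on both siControl 1 and siControl 2, or an exchange of the whole groups. By position alone, a swap of siControl 3 with a siCSRP2 array cannot be told apart from the labels as given. The upper quartile of siControl 3, 0.6922, lies above the lower quartile of siCSRP2 1 (0.49). The groupings that such a swap would make, with siCSRP2 1, 2 or 3, each gave 0 genes past the threshold, against 1093 as labelled. That argues against such a swap if the siRNA changed many genes, which was not tested. It does not bear on a wrong label of siControl 3 alone. A signal too near background for a fall to show, a probe set that does not report the CSRP2 transcript, a weak or passed knockdown at the time of RNA extraction, and a loss of protein without loss of RNA were not tested and stay open. On the first, the CSRP2 mean lay at percentile 73.4 of all genes, and 225 of 1488 genes with means of 3.71 to 4.30 fell. Those are other probe sets, and no background value of the CSRP2 probe set was at hand, so they do not decide it.

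Falls made up 89.1% of the genes called. That share depended on the scaling, at 76.03% after quantile normalization, 77.71% after cyclic loess and 94.5% after median centring. The deposited values were less spread on every siCSRP2 array (SD over probe sets 1.29 to 1.32) than on every siControl array (1.35 to 1.38). A difference in the spread of values between arrays and a brightness-dependent curve cannot be told apart from other causes: falls stayed in the majority with each array left out (69.7% to 90.1% after quantile normalization, 69.2% to 91.0% after cyclic loess), but the jackknife SE over arrays, 17.5 and 18.0 percentage points, is too large to decide. For the lists, a general fall of genes of like brightness is argued against by 0 of 10000 matched random lists with a median as low for mitosis, 0 for DNA replication and 14 for mesenchymal markers, though genes of a list are correlated and random ones are not; it cannot be told apart for SRF targets (407), NRF2 targets (576), actin assembly (695) and glycolysis (850), and it may account for the invadopodia (2474) and LIM (4730) medians. A biological response to the CSRP2 siRNA, which the design names, stays open and untested, as does an effect of this siRNA on other transcripts.

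The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1093 genes past the threshold and the highest other split 0; it gave 285 with a 2-fold change against 0; and it gave 13 gene lists against 11. In each case 1 split, the real one, reached the real count. Among the splits that also part 3 pairs of replicate numbers, the highest others were 0, 0 and 6, and the remaining splits part 1 pair.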

How the results depend on the processing

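The fits that join quantile or loess scaling with the replicate block were chosen after the data were seen. Genes past the threshold numbered 1093 (119 higher, 974 lower, 285 with a 2-fold change). With the replicate block they were 2348 (398 higher, 1950 lower), and with array weights, which gave siControl 3 the lowest weight (0.492), 2924 (597 higher, 2327 lower, 486 with 2-fold change). With the block and quantile normalization they were 2010 (524 higher, 1486 lower), and with the block and cyclic loess 2048 (531 higher, 1517 lower). Testing every probe set on its own gave 506 (51 higher, 455 lower). limma's fit without moderation gave 6 (1 higher, 5 lower, 0 with 2-fold change), where 2841 genes had an unadjusted p below 0.05. Higher genes were 210 after quantile normalization and 197 after cyclic loess, and lower genes 1471 after median centring. Leaving out 1 array, which leaves 2 against 3, gave 91 to 2620 genes (5 to 427 higher, 86 to 2193 lower, 73 to 627 with 2-fold change). The cause of these changes was not tested. For single probe sets, more tests bear on the lower count. The number of arrays alone does not account for the counts with 1 array left out. Fits of that size gave 877 genes without siCSRP2 1, 157 without siControl 1, 91 without siControl 2 and 2620 without siControl 3. The count was lowest where siControl 3, which lay between the groups, was 1 of 2 controls, and highest where it was left out. The dim filters, probe set means, intensity trend and robust moderation gave 1050 to 1290 genes.

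CSRP2 did not pass under any setting run (log2 difference -0.51 to -0.01, adjusted p 0.188 to 0.993). The number of lists called, 13 as reported, was 8 after quantile normalization or cyclic loess, with or without the replicate block, 7 with the dimmest 50% of genes left out, 0 with an estimated correlation (camera; 15 by fry, of which 8 were among the 13; 13 on ranks) and 10 to 14 with 1 array left out. Lists were not run under robust moderation or no moderation. The intensity trend ended the LIM, glycolysis, ribosomal and leukocyte calls, array weights the LIM, glycolysis and ribosomal calls, and the filter on the dimmest 25% the LIM and glycolysis calls. Testing every probe set ended the ribosomal and leukocyte calls and called YAP targets (median 0.05, against the test's direction), collagens, proteases, oxidative phosphorylation and heat shock lower. Of 140 named genes, 94 passed as reported and none changed direction under any setting. Calls lost numbered 93 without moderation, 59 over every probe set, 25 after quantile normalization, 22 after cyclic loess, 20 with the intensity trend, 11 and 10 with quantile or loess scaling plus the block, at most 3 under the other full sets of arrays, and 1 to 79 with 1 array left out. With the block 22 were gained and none was lost. The interferon list, not called, was called in 5 of 15 settings other than leaving out an array. The block changed no list call, and beyond the genes and member counts given it changed no other call. Without detection calls, signal over background is unknown, which limits the dimmest genes.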

Other observations

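The label and oxygen tests of siControl 3 below were chosen only after its place between the groups had been seen; the test of its mitosis genes was also chosen after that place was seen, but before the shift of those genes in siControl 3 was known.

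Falls were more frequent among brighter genes when genes were ranked by mean expression and cut into 10 bins of equal size. Bins 8 and 9 had median log2 differences of -0.24 and -0.25, with 225 and 282 genes that fell, and the brightest bin had -0.11, with 217 that fell and 47 that rose. The 4 dimmest bins had medians of 0.07 to 0.10 and at most 4 falls each. By biotype, 942 of 11916 protein-coding genes fell and 96 rose, 18 of 1398 long non-coding RNAs fell and 9 rose, and of 1072 microRNA genes 6 fell and 11 rose.

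siControl 3 stood apart from siControl 1 and 2 in more than 1 program. Its shift from the mean of the other controls had a median of 0.76 over immediate early genes, 0.65 over hypoxia and HIF targets, 0.44 over NF-kB genes, -0.57 over DNA replication and -0.46 over mitosis genes, each outside the 95% range of matched random lists. Over mesenchymal markers it was -0.08, inside that range (-0.29 to 0.19), where the siCSRP2 arrays lay at -0.60 from the same controls. Over all genes the median shift was -0.02.

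Why siControl 3 stood apart is open. One hypothesis is that fewer dividing cells in that culture may contribute, since 0 of 10000 matched random lists shifted as low as the mitosis list, and an oxygen-poorer or denser culture is a candidate explanation, since 0 of 10000 shifted as high as the hypoxia list; neither value shows a cause. A wrong label on siControl 3 cannot be told apart from these: a first test, its correlation with its own against the other group, left it level at 0.000404, and a second, added because the first did not decide, put its median position at 0.5209 between the other controls (0) and the siCSRP2 arrays (1). The quartiles of that position, 0.35 to 0.69, overlap those of siCSRP2 1 (0.49 to 0.95, median 0.72), which keeps the label open. The mesenchymal value of -0.08 lay with the other controls, but that list was singled out from results that counted siControl 3 as a control. On DNA replication (-0.57) and immediate early genes (0.76), siControl 3 lay near the siCSRP2 arrays (-0.67 and 0.72 from the same controls). The lists therefore do not decide the label.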
